A study of Mus musculus with 27 samples.

How the data were processed

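Liver RNA from 27 mice was measured on 27 Affymetrix arrays, 1 mouse liver per array, in 3 groups of 9 that the labels name Con, Veh and Dex. The labels do not spell these names out, and they are used here as written. The sex and strain of the mice, the dose and the time are not given either. Per the labels, the RNA was purified with Trizol and RNeasy columns, looked at on a Bioanalyzer for DNA and degradation, and turned into targets with the usual Affymetrix steps. The array type comes from the header of the probe annotation. The deposited table holds 1 linear intensity per probe set and array. Each array had a trimmed mean close to 100 (2% trimmed at each end, lowest 100.1, highest 100.2), so the authors' values had already been scaled by 1 factor per array. The software that summarised the probes, its version and the scaling target are not given in the sources used here.

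Because the highest and lowest trimmed means differed by less than 1.1-fold, no further scaling was applied. Values under the 10th percentile of all positive values (2.6) were set to it, and log2 was taken. A probe was tested when its intensity lay above the median of its array in at least 9 of the 27 arrays. The 66 control probes of the array were left out of the tests, which left 6784 probes for 5200 genes with a single symbol. The annotation gave 1 symbol for 10855 probes, several for 396 and none for 1237, and 688 of the tested probes had no single symbol. Where a gene had several tested probes, the 1 with the highest mean log2 intensity stood for it. Gene names came from the annotation and were compared by gene number with a reference gene table, which gave 10839 matches and changed 0 symbols. An array has no read depth, so the number of arrays and the signal over the floor limit the precision.

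Group means were fitted to all 27 arrays with limma 3.58.1 in R 4.3.3 (lmFit, 24 residual degrees of freedom), and Dex vs Veh, Veh vs Con and Dex vs Con were taken from the same fit (eBayes with a mean trend, two-sided, Benjamini-Hochberg over the 6784 probes, threshold 0.05). All changes are log2 values of the first group minus the second, and errors of changes are standard errors of the fit. The 3 comparisons share arrays, so overlaps between them are given beside values from simulated data without any group difference, from splits of the shared group into separate parts, and from independent draws.

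The 30 gene lists (564 genes, of which 332 had a tested probe) were fixed before the data were examined. They covered glucocorticoid-induced genes, which is 1 reading of the group name Dex, gluconeogenesis and amino acid catabolism, targets of PXR and CAR, of NRF2 and of PPARA, lipogenesis, cholesterol synthesis, bile acids, the acute phase response, complement and coagulation, NF-kB, interferon-stimulated genes, the circadian clock, endoplasmic reticulum stress, heat shock, the cell cycle, immediate early genes, the growth hormone axis, MHC class II, and markers of T and NK cells, B cells, macrophages, neutrophils, endothelium, stellate cells, bile ducts, red cells, exocrine pancreas, adipocytes and skeletal muscle. Lists with at least 4 measured members (27 of 30) were tested with limma's camera (correlation preset to 0.01, mean trend kept, two-sided, Benjamini-Hochberg over the 27 lists of a comparison), and each list's members were also adjusted over the list alone. The design asked for the same fit as the probes. An early look at the data used camera without the mean trend, and the trend setting was settled after that look. A symbol alias for 1 gene of the gluconeogenesis and glucocorticoid lists was also added after the files were seen. Some lists share members, so their tests are not independent. The glucocorticoid list shares Tat, Tdo2 and Pck1 with the gluconeogenesis list, and Lcn2 and Mt1 with the acute phase list, among others. A list score is the mean log2 intensity of the members of a list in an array, minus the mean of the 9 Con arrays.

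The genes named were set by a rule fixed beforehand: in each comparison the 10 genes with the largest rise and the 10 with the largest fall among single-symbol probes past the threshold (5 and 5 for Dex vs Con), up to 3 members with the smallest p of each list past the test, and Tat, Pck1, Tsc22d3, Fkbp5, Per1, Igfbp1, Mt1, Cyp3a11, Gapdh and Actb throughout. Tsc22d3 and Gapdh had no tested probe with a single symbol.

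Array quality was compared between groups with two-sided exact permutation tests of the group means (all 48620 splits of 18 arrays, Benjamini-Hochberg over the measures). The measures were the 3' to 5' control probe ratios of Gapdh and beta-actin, the trimmed mean, the median intensity and the share of probes at or under the floor. The signals of 3 control probes (18S, CreX and BioB) were added after the data were seen.

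The alternatives planned before the data were examined were quantile normalization, floors at percentiles 1 and 20, no filter or a stricter filter, the replicate number as a block, a fit of only the 2 groups compared, array weights, robust moderation, no mean trend, the Gapdh ratio as a covariate, stricter thresholds, fry, an estimated correlation between genes, the mean of all probes of a gene, and leaving out each array in turn for probes and named genes. Robust moderation does not exist for camera, so it was not run for the lists. The beta-actin ratio and the array median as covariates, the set without the least correlated array of each group, and leaving out each array in turn for the lists were added later. Matching replicate numbers gave no pairing: the correlation of same-numbered arrays, after removing group means, was above 0.1 in 4 of 27 cases, between -0.195 and 0.187. The pipeline was tested on simulated data with 200 of the 6784 probes changed. A log2 change of 1 was recovered in 70%, 62% and 67% of the changed probes for Dex vs Veh, Veh vs Con and Dex vs Con, and a change of 2 in 94%, 94% and 96%, with 5.20%, 1.89% and 5.23% of calls false. A shift of 1 in all members of the glucocorticoid list was called in the 3 comparisons, with 1, 0 and 0 other lists called. The simulated probes were independent of each other and had the same spread in each group. The measured groups differed in spread, and in them no list passed with an estimated correlation between genes. These simulated rates therefore do not test the preset correlation or the shared spread. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.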

Results

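The data are the liver expression profiles of 27 mice in 3 groups of 9, named Con, Veh and Dex. The series gives no purpose beyond naming the 3 treatments. Each array measured 1 liver. The median intensity of an array lay between 17.6 and 33.2, and between 5.18% and 15.1% of the probes were at or under the floor. The median standard deviation of a probe within a group was 0.375 in Con, 0.469 in Veh and 0.566 in Dex (log2, 9 arrays each). Spearman correlations between 2 arrays ranged from 0.793 to 0.937, and no 2 arrays were identical. The first principal component held 20% of the variance and the second 8.44%.

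RNA quality differed between Veh and Dex. The log2 ratio of the 3' to the 5' control probe of beta-actin, which grows as RNA is degraded or targets are shortened, was 1.27 ± 0.318 in Veh and 0.886 ± 0.169 in Dex (SD, n = 9 each, two-sided exact permutation adjusted p = 0.00761). The Gapdh ratio was 0.50 ± 0.251 in Veh and 0.237 ± 0.157 in Dex (SD, n = 9 each, exact adjusted p = 0.0355). In Con the ratios were 0.947 ± 0.243 and 0.354 ± 0.116. The beta-actin ratio did not pass the test between Veh and Con (exact adjusted p = 0.0590), and neither ratio passed between Dex and Con (exact adjusted p = 0.675 and 0.223). The median intensity was 28.1 in Con, 23.4 in Veh and 24.7 in Dex, and did not pass the test between Veh and Con (exact adjusted p = 0.0590). The trimmed means passed it for Veh and for Dex against Con (exact adjusted p = 0.00452 and 0.0158) with differences of 0.02 on a scale of 100. The 18S, CreX and BioB controls did not pass the test between any 2 groups.

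**Figure D1:**
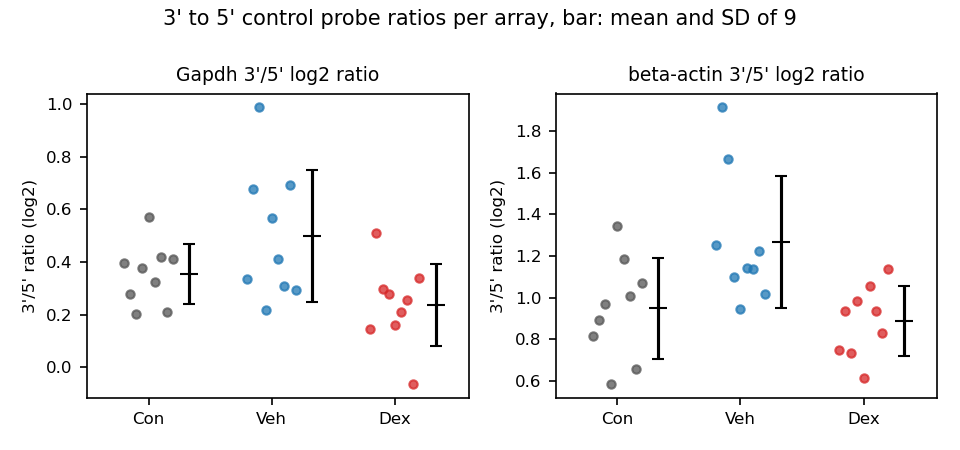
The 3' to 5' control probe ratios (log2) of Gapdh and beta-actin in each array, by group. Points are single mice and bars are the mean and SD of 9. The Veh arrays have the highest mean of both ratios, 0.50 and 1.27.

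The comparison of Dex with Veh asked what the Dex treatment changed relative to the group nearest to it in name. Among genes past the threshold, those that fell most in Dex livers included 3 interferon-stimulated genes. Isg15, a ubiquitin-like protein induced by interferon, fell by 1.84 ± 0.36 on the log2 scale (SE, 9 mice per group, limma adjusted p = 0.0226), the immunity GTPase gene Igtp fell by 2.13 ± 0.49 (0.0487) and the immunoproteasome subunit Psmb8 fell by 1.32 ± 0.29 (0.0440). All 9 Dex mice lay below the Veh median for each of these genes. Of the 27 sets that leave out 1 array, the call held in 27 for Isg15, 10 for Psmb8 (adjusted p up to 0.0807) and 6 for Igtp (up to 0.0972). Tff3, a secreted trefoil peptide, rose by 3.53 ± 0.76 (0.0440), with all 9 Dex mice above the Veh median, and its call held in 15 of those sets (adjusted p up to 0.0807). Its log2 intensity lay between 2.77 and 4.54 in 8 of 9 Veh mice, which is not clearly above background, so the size of this rise depends on weak signals.

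In this comparison 18 of the 6784 probes changed, 3 higher and 15 lower, which stood for 12 genes with a single symbol, and 1029 probes had an unadjusted p under 0.05. The other genes that rose were the sulfotransferase Sult1d1 (1.72 ± 0.34, adjusted p = 0.0226, 8 of 9 Dex mice above the Veh median) and the transcription factor Usf1 (0.86 ± 0.16, 0.0226, 9 of 9), whose second probe changed by 0.33 (adjusted p = 0.514). The other genes that fell were Gatm of creatine synthesis (-1.13 ± 0.25, 0.0440), the lipid antigen presenting Cd1d1 (-1.12 ± 0.25, 0.0440), the proteasome activator Psme1 (-0.83 ± 0.17, 0.0308), the vitamin E carrier Afm (-0.72 ± 0.14, 0.0226), the chemerin gene Rarres2 (-0.60 ± 0.14, 0.0499) and the actin branching factor Arpc2 (-0.58 ± 0.13, 0.0452). Each lay below the Veh median in all 9 Dex mice except Cd1d1, with 8 of 9. The count moved by over 1.5 times when 1 of 21 arrays was left out. It was 4 without Dex 5, 5 without Dex 3, 6 without Dex 2, Veh 2 or Veh 5, 8 without Con 8 or Veh 4, and 9 without Con 1, Con 4, Con 5, Con 6, Veh 3 or Veh 9. It was 10 without Con 2, Con 3, Con 7, Dex 4 or Dex 7, 58 without Dex 9, 59 without Dex 8 and 124 without Dex 6. Of the 12 genes, Afm, Isg15 and Usf1 passed in each of the 27 sets that leave out 1 array. Of the 12 named calls 8 held with quantile normalization. With the beta-actin ratio as a covariate 1 probe passed, and in a fit of only the 2 groups 1 probe passed.

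The interferon-stimulated list fell as a group in Dex vs Veh (camera adjusted p = 6.27e-09; adjusted p = 0.331 with an estimated correlation). All 12 measured members were lower, with a median log2 change of -1.23. Of these, 3 passed over all probes and 10 when adjusted over the list alone. The list passed with fry as well (adjusted p = 0.0175). Glucocorticoid-induced genes rose as a group (adjusted p = 2.50e-07; adjusted p = 0.331 with an estimated correlation, 0.130 with fry). Of 24 members 22 were higher, with a median of 0.47. Of these, 0 passed over all probes and 6 when adjusted over the list alone. The members with the smallest p were Tdo2 (0.97, adjusted p = 0.0597), Tat (1.12, 0.0643) and Ddit4 (1.97, 0.0892), with 9, 9 and 8 of 9 Dex mice above the Veh median. Ddit4 had a mean log2 intensity of 3.87 in Veh, which is not clearly above background. The size of its rise depends on weak signals. The list score was 2.43, 2.52 and 2.49 in Dex 1, Dex 2 and Dex 3, and between -0.19 and 0.52 in the other 6 Dex mice. In Veh it lay between -0.46 and 0.71, and in Con between -0.50 and 0.61. Whether the replicate numbers stand for different times, doses or batches is not given in the sources used here, so each Dex mean is over 9 mice whose equal treatment is not known.

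Macrophage and Kupffer cell markers fell as a group in Dex vs Veh (adjusted p = 0.00192; adjusted p = 0.396 with an estimated correlation, 0.130 with fry). All 13 members were lower, with a median of -0.53, while 0 passed over all probes and 2 when adjusted over the list alone. The smallest p belonged to Cd5l (-0.91), Ctss (-1.02) and Mrc1 (-0.60), and the first 2 had an adjusted p of 0.118. Mrc1 had a mean log2 intensity of 4.61 in Dex, which is not clearly above background. Targets of PPARA, the receptor that switches on fatty acid oxidation, fell as a group (adjusted p = 0.00307; adjusted p = 0.331 with an estimated correlation, 0.0645 with fry). Of 20 members 16 were lower, with a median of -0.37, while 0 passed over all probes and 5 when adjusted over the list alone. Its members with the smallest p were Decr1 (-0.83), Acaa1b (-0.97) and Acaa1a (-0.66, adjusted p = 0.102). Cyp4a10 and Cyp4a14 were among the 4 members that went the other way. Their mean log2 intensities were 7.31 and 7.63 in Veh, and 7.73 and 8.80 in Dex. With the stricter filter the adjusted p of both the PPARA and the macrophage list went over the threshold (0.0667 and 0.0621), and that of the macrophage list did so without the least correlated array of each group (0.0686).

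Complement and coagulation genes fell at the edge of the threshold in Dex vs Veh (adjusted p = 0.0494; adjusted p = 0.331 with an estimated correlation, 0.0217 with fry). Of 20 members 16 were lower, with a median of -0.17. Of these, 0 passed over all probes and 1, F13b (-0.58), when adjusted over the list alone. Mbl2 (-0.57) and Mbl1 (-0.40) followed. Without a mean trend the adjusted p was 0.0658, and with the Gapdh or beta-actin ratio as a covariate it was 0.149 or 0.154. Leaving out any 1 of 15 arrays ended the call. The adjusted p was 0.0506 without Con 1, 0.0536 without Con 3, 0.0508 without Con 4, 0.0534 without Con 5, 0.0512 without Con 6, 0.0528 without Con 8, 0.0501 without Con 9, 0.0890 without Veh 1, 0.0514 without Veh 4, 0.0513 without Veh 7 and 0.0732 without Veh 8. It was 0.0923 without Dex 3, 0.102 without Dex 6, 0.133 without Dex 8 and 0.0654 without Dex 9.

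Of the genes fixed beforehand, Fkbp5 (1.98 ± 0.65, adjusted p = 0.139), Mt1 (2.91 ± 1.16, 0.219), Per1 (0.88, 0.412), Igfbp1 (0.64, 0.738), Pck1 (0.33), Cyp3a11 (0.23) and the control gene Actb (0.36 ± 0.46) did not pass the test in Dex vs Veh. The beta-actin and Gapdh 3' to 5' ratios were lower in Dex than in Veh. The changes of the 5 lists that passed in this comparison are therefore partly confounded with RNA quality. Whether the list scores followed the ratios from mouse to mouse was not tested. With the beta-actin ratio in the fit 4 of these 5 lists kept their calls, with an adjusted p of 1.10e-05 for interferon, 6.28e-06 for glucocorticoid, 4.20e-05 for macrophage and 0.0454 for PPARA. With the Gapdh ratio the values were 3.08e-07, 1.35e-10, 3.77e-06 and 0.0172, and the complement list lost its call with either ratio. With an estimated correlation instead, none of the 5 passed (adjusted p = 0.396 for macrophage and 0.331 for the others).

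**Figure D2:**
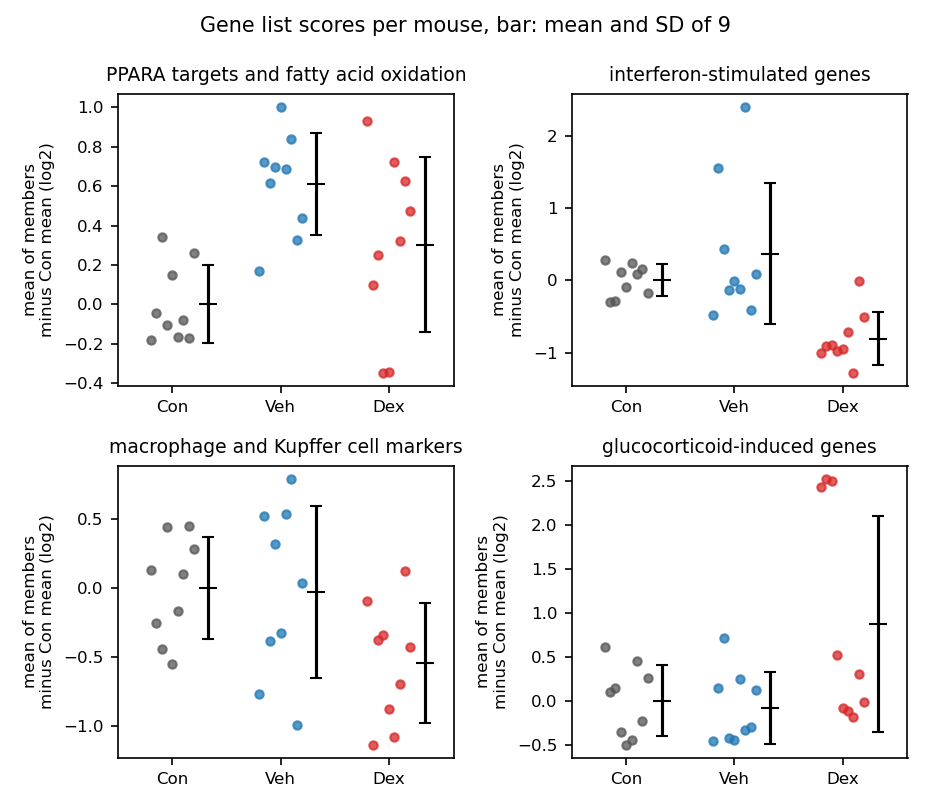
Scores of 4 gene lists in each mouse (mean log2 intensity of the measured members minus the mean of the Con group), by group. Points are single mice and bars are the mean and SD of 9. The glucocorticoid score is above 2.4 in 3 Dex mice and at most 0.52 in the other 6, and the interferon score is below the lowest Con mouse in 8 of 9 Dex mice.

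The comparison of Veh with Con asked how the livers of the Veh group differed from those of the Con group. Among genes past the threshold, the largest rises in Veh livers included genes of fatty acid and drug metabolism. The fatty acid hydroxylases Cyp4a10 and Cyp4a14, classical PPARA targets, rose by 3.14 ± 0.54 and 3.09 ± 0.61 on the log2 scale (SE, 9 mice per group, limma adjusted p = 0.00200 and 0.00674), and all 9 Veh mice lay above the Con median for both. Their mean log2 intensities in Con were 4.17 and 4.54, which is not clearly above background. The sizes of these rises therefore depend on weak signals. Cyp2b9, a member of the PXR and CAR list, rose (limma adjusted p = 0.00196), in 8 of 9 Veh mice above the Con median. Its mean intensity in Con was 5.99 ± 5.88 (SD, n = 9), close to the floor of 2.6, so it was not clearly above background there. The size of the change, 6.06 ± 1.04 as fitted, depends on the floor. Cyp7b1, which hydroxylates oxysterols and is higher in male liver, fell by 2.71 ± 0.58 (0.00925), and all 9 Veh mice lay below the Con median. The fall was uneven: Cyp7b1 was at 5.43, 5.61, 5.81 and 6.24 (log2 intensity) in Veh 2, Veh 4, Veh 5 and Veh 7 and between 7.83 and 9.74 in the other 5, against a Con mean of 10.31. Cyp2b9 was between 10.11 and 11.68 in the same 4 mice and at most 8.79 in the other 5.

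In Veh vs Con 262 of 6784 probes changed, 81 higher and 181 lower (30.9% higher), which stood for 219 genes with a single symbol, and 1598 probes had an unadjusted p under 0.05. With quantile normalization 85 probes changed and 52.9% were higher, and 14 of the 21 named calls held. The median change over all tested probes was -0.19 in Veh vs Con and -0.20 in Dex vs Con, and with quantile normalization it was -0.02 and -0.04. Changes against Con are therefore 0.19 and 0.20 higher relative to the median probe than the fitted values given here. The count moved by over 1.5 times when 1 of 12 arrays was left out. It was 85 without Veh 5, 93 without Veh 2, 106 without Con 3, 112 without Con 7, 118 without Con 1, 122 without Veh 4, 145 without Con 8, 147 without Con 6, 155 without Con 9, 167 without Veh 1, 174 without Con 4 and 586 without Veh 9. The count was 75 with the Gapdh ratio as a covariate, 33 with the beta-actin ratio and 21 with the array median. It was 656 in a fit of only the 2 groups and 1158 with array weights.

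Among genes past the threshold, the other largest rises in Veh vs Con were those of Cyp2c39 (1.52 ± 0.33), the acute phase glycoprotein Orm3 (1.47 ± 0.34), Crip1 (1.28 ± 0.34), the glutathione transferase Mgst3 (1.16 ± 0.33), the actin-binding thymosins Tmsb4x (1.13 ± 0.25) and Tmsb10 (1.06 ± 0.29), and Cyp2c38 (1.01 ± 0.21). Their adjusted p lay between 0.00781 (Cyp2c38) and 0.0421 (Mgst3), with 7 (Orm3) to 9 Veh mice above the Con median. Crip1 and Orm3 had mean log2 intensities of 3.69 and 4.60 in Con, which is not clearly above background. The sizes of these 2 rises depend on weak signals. Among genes past the threshold, the largest falls after Cyp7b1 were those of Hnrnpl (-1.83 ± 0.45), the nucleoside diphosphate kinase Nme1 (-1.74 ± 0.27, adjusted p = 8.40e-04), the fatty acid elongase Elovl2 (-1.71 ± 0.40), Phospho2 (-1.63 ± 0.37), Hsd3b6 (-1.60 ± 0.43), Etfbkmt (-1.48 ± 0.32), Apbb1 (-1.45 ± 0.36), Dnajb13 (-1.42 ± 0.33) and Nxf1 (-1.38 ± 0.35). Except Nme1 these had adjusted p between 0.0103 (Etfbkmt) and 0.0347 (Hsd3b6). Hsd3b5 (-3.45, adjusted p = 0.0694) and Hsd3b2 (-2.11, 0.0530) fell further without passing. For Apbb1 and Elovl2, 8 of 9 Veh mice lay below the Con median, and 9 of 9 for the others. Mean log2 intensity in Veh was 3.71 for Phospho2, 3.93 for Nxf1, 4.16 for Hnrnpl, 4.54 for Apbb1 and 4.76 for Nme1. These levels are not clearly above background, so the sizes of these falls depend on weak signals. The second probe passed for Cyp7b1 (-3.09, adjusted p = 0.00188) and not for Nme1 (-0.52, 0.20) and Dnajb13 (-0.63, 0.361). Leaving out 1 array at a time kept the call of Mgst3 in 15 of 27 sets, Tmsb10 in 16, Crip1 and Hsd3b6 in 17, Nxf1 in 22, Hnrnpl in 25 and Apbb1 in 26. The highest adjusted p were 0.0957 for Mgst3 (without Veh 5), 0.0798 for Tmsb10 and 0.0817 for Hsd3b6 (without Veh 2), and 0.0658 for Crip1 (without Veh 4).

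PPARA targets rose as a group in Veh vs Con (camera adjusted p = 3.49e-09; adjusted p = 0.0621 with an estimated correlation, 0.0276 with fry). Of 20 members 18 were higher, with a median log2 change of 0.42, or 0.61 relative to the median probe. Of these, 3 rose over all probes (Cyp4a10, Cyp4a14 and the enoyl-CoA isomerase Eci1, 0.56 ± 0.14, adjusted p = 0.0281, kept in 22 of 27 sets that leave out 1 array), and 8 rose and 1 fell when adjusted over the list alone. Lipogenesis genes rose as a group (adjusted p = 2.77e-05; adjusted p = 0.474 with an estimated correlation, 0.178 with fry). All 12 members were higher, with a median of 0.42. Of these, 0 passed over all probes and 2, Elovl6 (1.69 ± 0.51, adjusted p = 0.0558) and Fasn (1.20 ± 0.39, 0.0723), when adjusted over the list alone. Elovl5 was next (0.59, 0.161).

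Targets of PXR and CAR, receptors that induce drug metabolism, rose in Veh vs Con (adjusted p = 5.15e-05; adjusted p = 0.137 with an estimated correlation, 0.140 with fry). Of 14 members 10 were higher, with a median of 0.23. Of these, 3 rose over all probes (Cyp2b9, Cyp2c38 and Cyp2c39), and 4 rose and 1 fell when adjusted over the list alone. The list score was 1.04, 1.30, 1.21 and 1.05 in Veh 2, Veh 4, Veh 5 and Veh 7, the mice with the lowest Cyp7b1. In the other Veh mice it lay between -0.13 and 0.79, and in Con between -0.33 and 0.26. Acute phase genes rose as a group (adjusted p = 5.15e-05; adjusted p = 0.574 with an estimated correlation, 0.451 with fry). Of 24 members 17 were higher, with a median of 0.29. Of these, 1 (Orm3) passed over all probes and 1 when adjusted over the list alone. Lcn2 (2.19 ± 0.97, adjusted p = 0.165, second probe -0.55) and Hamp (0.43 ± 0.20, 0.178) did not pass. With quantile normalization the adjusted p of the acute phase list was 0.141.

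Interferon-stimulated genes and MHC class II genes rose as groups in Veh vs Con, and both calls rested on single mice. The interferon list had an adjusted p of 0.00190 (adjusted p = 0.574 with an estimated correlation, 0.451 with fry) and 0.0827 without Veh 7. Of 12 members 10 were higher, with a median of 0.38, and 0 passed over all probes or when adjusted over the list alone. Iigp1 (0.83), Isg15 (0.82) and Psmb8 (0.74) had the smallest p, with adjusted p of 0.144, 0.161 and 0.127. The MHC class II list had an adjusted p of 0.0245 (adjusted p = 0.544 with an estimated correlation, 0.377 with fry). It was 0.111 without Veh 7, 0.0520 without Veh 2 and 0.0648 without Con 1. Of 7 members 5 were higher, with a median of 0.80, while 0 passed over all probes and 4 when adjusted over the list alone. They include H2-Aa (1.15), Cd74 (0.92) and H2-DMa (0.82). The beta-actin ratio as a covariate ended both calls (adjusted p = 0.0869 for interferon, 0.0566 for MHC class II).

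Of the genes fixed beforehand, none of Igfbp1 (1.74 ± 0.83, adjusted p = 0.201), Cyp3a11 (0.29, 0.251), Tat (0.06), Mt1 (-0.18), Actb (-0.35), Per1 (-0.36), Fkbp5 (-0.56) and Pck1 (-0.73, 0.33) passed in Veh vs Con. The sign of Tat turned with quantile normalization (-0.18), with the Gapdh ratio (-0.13) and with the array median (-0.05) in the fit.

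**Figure D3:**
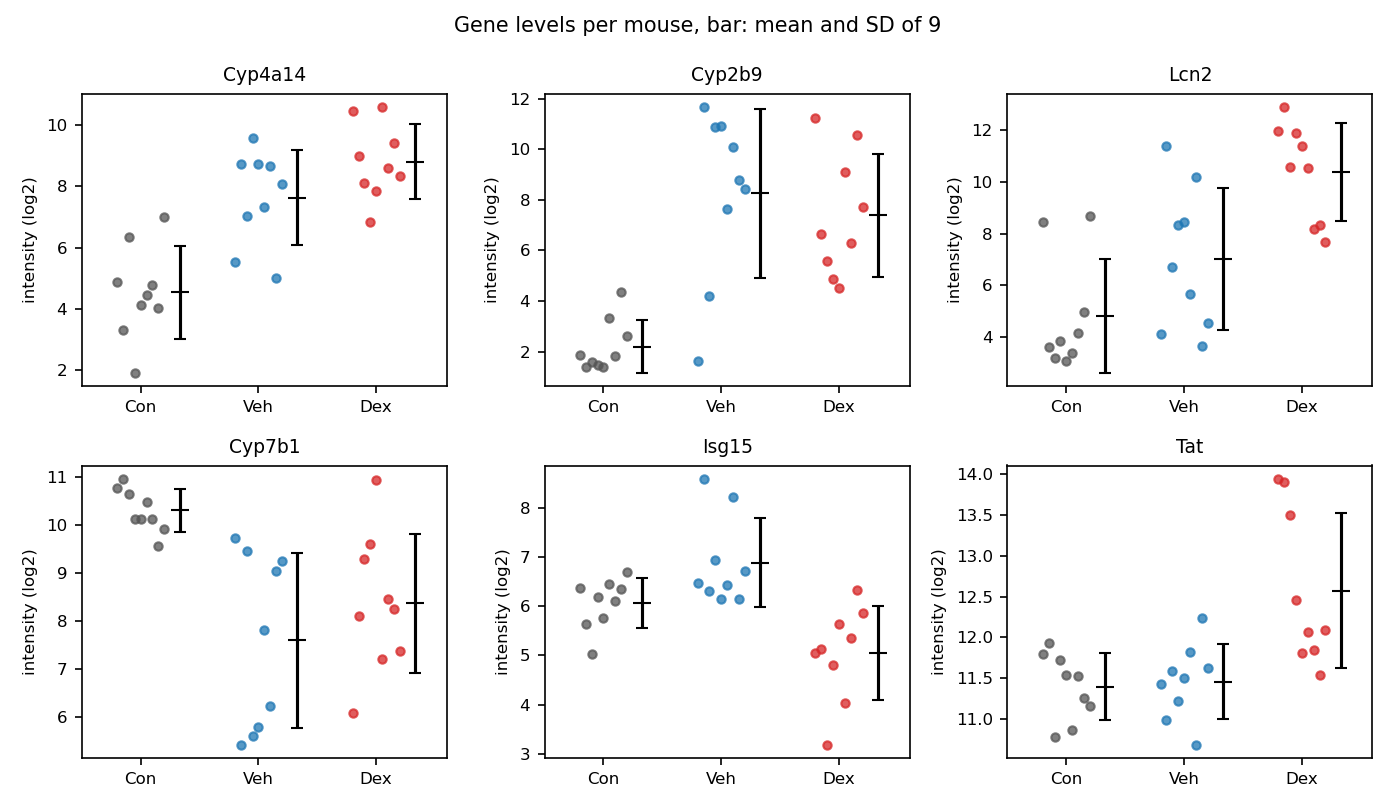
Log2 intensity of 6 genes in each mouse, by group. Points are single mice and bars are the mean and SD of 9. Cyp4a14 and Cyp2b9 are higher in Veh and Dex than in Con, Lcn2 passed only in Dex vs Con of the 3 comparisons, Cyp7b1 is lower in Veh and Dex, Isg15 is lower in Dex than in Veh, and Tat is highest in 3 Dex mice.

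The comparison of Dex with Con asked what the Dex treatment changed relative to the Con group. Among genes past the threshold, the largest rises in Dex livers included an acute phase gene and cytochromes P450, and the largest falls included genes of steroid and thyroid hormone metabolism. The iron-binding acute phase protein Lcn2 rose by 5.56 ± 0.97 on the log2 scale (SE, 9 mice per group, limma adjusted p = 5.95e-04), with a change of 0.04 on its second probe. Its log2 intensity lay between 3.09 and 4.97 in 7 of 9 Con mice, which is not clearly above background, and at 8.46 and 8.69 in Con 1 and Con 9, so the size of this rise depends on weak signals. Cyp2b9 rose as well (0.00183), by a fitted 5.19 ± 1.04 that depends on the floor, since it was not clearly above background in Con. Cyp4a14 rose by 4.26 ± 0.61 (1.98e-04), the CAR target Cyp2b10 by 3.98 ± 0.69 (5.67e-04) and Cyp4a10 by 3.56 ± 0.54 (2.22e-04), and for these 4 genes 9 of 9 Dex mice lay above the Con median. Cyp4a14 and Cyp4a10 had mean log2 intensities of 4.54 and 4.17 in Con, which is not clearly above background. The sizes of their rises depend on weak signals too. Cyp2b10 was at 12.34, 11.80 and 12.30 (log2 intensity) in Dex 1, Dex 2 and Dex 3, the mice with the high glucocorticoid scores, and between 6.85 and 9.74 in the other 6, with a Con mean of 5.33. The largest falls past the threshold were in the male-biased Hsd3b5 (-3.48 ± 1.11, adjusted p = 0.0321), the thyroid hormone deiodinase Dio1 (-2.37 ± 0.71, 0.0239), Elovl2 (-2.27 ± 0.40, 6.78e-04), Hsd3b2 (-2.16 ± 0.63, 0.0203) and the heme synthesis enzyme Alas2 (-1.97 ± 0.56, 0.0178). Between 8 and 9 of 9 Dex mice lay below the Con median for these. The call of Hsd3b5 ended without Dex 1 (0.0766) or Dex 2 (0.0738), and that of Dio1 without Dex 4 (0.0525). For Hsd3b5 and Dio1, 1 Dex mouse was at the floor. Dio1 had a mean log2 intensity of 4.34 in Dex, which is not clearly above background. The size of its fall depends on weak signals. Alas2 is also a member of the red cell list, and its SD was 1.93 in Dex and 0.344 in Con. Whether its fall came from liver cells or from red cells was not tested.

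In Dex vs Con 1115 of 6784 probes changed, 221 higher and 894 lower (19.8% higher), which stood for 950 genes with a single symbol, and 2138 probes had an unadjusted p under 0.05. With quantile normalization 658 probes changed and 29.3% were higher, and 18 of the 24 named calls held. Leaving out 1 array at a time gave from 785 (without Dex 1) to 1488 (without Dex 8).

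PXR and CAR targets rose as a group in Dex vs Con (camera adjusted p = 5.59e-07; adjusted p = 0.0582 with an estimated correlation, 0.00638 with fry). Of 14 members 11 were higher, with a median log2 change of 0.58, or 0.78 relative to the median probe. The list score lay between 0.52 and 2.01 in the 9 Dex mice and was at most 0.26 in Con. Of these, 8 rose and 1 fell over all probes, and 8 rose and 1 fell when adjusted over the list alone. They include Cyp2b10, which was highest in Dex 1, Dex 2 and Dex 3, Cyp2c38 (1.29 ± 0.21, adjusted p = 3.09e-04), Cyp3a11 (0.52 ± 0.15, 0.0214) and, falling, the canalicular transporter Abcc2 (-1.12 ± 0.21, 0.00108), all with 9 of 9 Dex mice on the side of the change. With quantile normalization Cyp3a11 did not pass (0.22, 0.295). Acute phase genes rose as a group (adjusted p = 5.59e-07; adjusted p = 0.4931 with an estimated correlation, 0.192 with fry). Of 24 members 18 were higher, with a median of 0.41. Of these, 6 rose over all probes and 7 when adjusted over the list alone, among them Lcn2, Orm3 (2.16 ± 0.34, 3.09e-04) and the protease inhibitor Serpina3n (1.07 ± 0.28, 0.0118). Orm3 had a mean log2 intensity of 4.60 in Con, not clearly above background. The acute phase score was 1.38, 2.43, 0.97 and 1.30 in Dex 1, Dex 2, Dex 3 and Dex 4. In the other Dex mice it lay between 0.23 and 0.44, and in Con between -0.73 and 1.04.

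Glucocorticoid-induced genes rose as a group in Dex vs Con (adjusted p = 1.46e-06; adjusted p = 0.4931 with an estimated correlation, 0.252 with fry). Of 24 members 20 were higher, with a median of 0.39. Of these, 5 rose over all probes and 5 when adjusted over the list alone, among them Lcn2, the tyrosine aminotransferase Tat (1.18 ± 0.28, adjusted p = 0.00705, 9 of 9 Dex mice above the Con median), the tryptophan dioxygenase Tdo2 (0.70 ± 0.23, 0.0371, 7 of 9) and Igfbp1 (2.39 ± 0.83, 0.0469, 7 of 9). Igfbp1 had a mean log2 intensity of 3.85 in Con, with 1 Con mouse at the floor. This is not clearly above background, so the size of its rise depends on weak signals. Leaving out 1 array at a time kept the call of Tdo2 in 19 of 27 sets and that of Igfbp1 in 12, with the highest adjusted p without Dex 2 (0.0885) and without Dex 1 (0.109). With quantile normalization Tdo2 did not pass (0.33, 0.326), and its second probe had a value of 0.35 (0.538) in the fit. The list score lay above the highest Con mouse (0.61) in 3 of 9 Dex mice, Dex 1, Dex 2 and Dex 3, and in the other 6 it lay within the Con range. Gluconeogenesis and amino acid catabolism rose as a group (adjusted p = 0.0146; adjusted p = 0.4931 with an estimated correlation, 0.284 with fry), and the adjusted p was 0.0501 without Dex 1. With quantile normalization it was 0.546. Of 17 members 10 were higher, with a median of 0.19. Of these, 4 rose and 2 fell over all probes, and likewise when adjusted over the list alone. They include the urea cycle enzyme Cps1 (0.75 ± 0.18, 0.00606), Tat, and Glud1 (-0.72 ± 0.19, 0.0117). The glucocorticoid list shares members such as Tat and Tdo2 with this list, and Lcn2 with the acute phase list. The calls of these lists are therefore not independent.

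Cholesterol synthesis genes rose as a group in Dex vs Con (adjusted p = 0.00392; adjusted p = 0.592 with an estimated correlation, 0.463 with fry). Of 16 members 12 were higher, with a median of 0.28. Over all probes 1 rose, Fdps (0.98 ± 0.25, adjusted p = 0.00966), and 1 fell, Sc5d (-1.31 ± 0.39, 0.0238, second probe -0.69, 0.224), while 3 rose and 1 fell when adjusted over the list alone. Mvk did not pass (0.52, 0.0573). The call of Sc5d ended without Dex 1 (0.0550) or Dex 2 (0.0502). Lipogenesis genes rose as a group (adjusted p = 0.00921; adjusted p = 0.592 with an estimated correlation, 0.474 with fry), and the adjusted p was 0.0757 without Dex 6 and 0.249 with quantile normalization. Of 12 members 9 were higher, with a median of 0.24. Of these, 1, Elovl6 (1.59 ± 0.51, 0.0315, kept in 19 of 27 sets that leave out 1 array, second probe 1.09, 0.109), passed over all probes and 1 when adjusted over the list alone, while Fasn (0.85, 0.135) and Thrsp (0.62, 0.215) did not.

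PPARA targets passed the test upwards in Dex vs Con (adjusted p = 0.0475; adjusted p = 0.592 with an estimated correlation, 0.633 with fry), but their median change was -0.05 and their mean 0.30. Of 20 members 9 were higher. Over all probes 3 rose, among them Cyp4a10 and Cyp4a14, and 2 fell, among them the acyl-CoA dehydrogenase Acadl (-1.44 ± 0.30, adjusted p = 0.00288), and the counts were 3 and 2 when adjusted over the list alone. The adjusted p was 0.562 with quantile normalization. It was 0.170 without Dex 1, 0.0999 without Dex 6, 0.0577 without Dex 7, 0.0689 without Dex 8, 0.0761 without Dex 9, 0.0973 without Con 1, 0.0579 without Con 4, 0.0735 without Con 6, 0.0632 without Con 7 and 0.0840 without Con 8. Interferon-stimulated genes did not pass as a list (adjusted p = 0.0648), although all 12 were lower, 3 passed over all probes and 6 when adjusted over the list alone. The adjusted p was 0.0362 with quantile normalization, 0.0146 without Veh 7, 0.0330 without Con 3, 0.0463 without Veh 2 and 0.0466 without Dex 2. Mt1 (2.74, 0.10), Fkbp5 (1.43, 0.126), Per1 (0.52), Actb (0.01) and Pck1 (-0.40) did not pass. The sign of Actb turned with quantile normalization (-0.15).

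The changes of Veh and of Dex against Con shared 56 probes that rose and 100 that fell, against 2.64 and 23.9 for independent draws, a value that is too low because both comparisons use the same Con arrays. Their log2 changes correlated across probes with r = 0.64, against 0.50 in simulated data and 0.45 when the 2 comparisons used separate Con arrays. Probes are not independent replicates. The covariance was 0.137, against 0.0438 in simulated data. Dex vs Veh and Veh vs Con had r = -0.27, against -0.50 in simulated data and -0.04 with separate Veh arrays, and 2 probes were lower in the first and higher in the second (0.179 for independent draws). When the 9 Veh mice were split so that each comparison used its own, the 2 changes had opposite signs in 126 of 126 splits for the PPARA list, 97 for the interferon list, 81 for the glucocorticoid list and 56 for the macrophage list. The splits are not independent. In 1000 simulations without change the mean was 63.5, and 4.3% of them reached 126 and 25.4% reached 97. The simulations gave each group the same spread. The SD of the interferon score was 0.219 in Con, 0.974 in Veh and 0.366 in Dex, and that of the PPARA score 0.199, 0.259 and 0.446. These shares therefore do not test the split counts. Whether a gene or list that passed in 1 comparison and not in another differed between them was not tested.

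Of the 27 lists tested, 16 passed in none of the comparisons. Their smallest adjusted p over the 3 comparisons was 0.105 for exocrine pancreas markers, 0.108 for the circadian clock and for B cell markers, 0.145 for immediate early genes, 0.169 for T and NK cell markers, 0.168 for NF-kB and inflammatory cytokines, 0.226 for endoplasmic reticulum stress and 0.234 for heat shock. It was 0.326 for the growth hormone axis, 0.33 for skeletal muscle, 0.340 for endothelium and for the cell cycle, 0.484 for red cells, 0.536 for bile acids, 0.664 for stellate cells and 0.849 for NRF2 targets. With quantile normalization the growth hormone list fell in Veh vs Con (camera adjusted p = 0.00866). In the main fit of Veh vs Con, 2 of its 15 members fell over all probes and 5 when adjusted over the list alone. Its score was -1.75, -1.11, -1.30 and -1.30 in Veh 2, Veh 4, Veh 5 and Veh 7. In the other Veh mice it lay between -0.29 and -0.15, and in Con between -0.41 and 0.41. Neutrophil and adipocyte markers with 3 measured members and bile duct markers with 1 were not tested, and had median changes in Dex vs Veh of 0.84, -0.35 and 0.00. All 3 neutrophil markers were higher in that comparison, and 0 passed over all probes and 3 when adjusted over the list alone. In Veh vs Con all 3 were lower, and 1 passed over all probes and 1 when adjusted over the list alone. The sign of the test differed from that of the median or mean in 4, 12 and 11 of the 27 lists in Dex vs Veh, Veh vs Con and Dex vs Con, and 0, 0 and 1 of these lists passed.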

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

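The tests of array scaling, RNA quality, a few arrays and other groupings of the mice were chosen after the results they test were seen, while those of the Cyp4a family and of fewer macrophages were written before.

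Among 185 groups of 9 values (the named genes in the groups compared, and the 5 array measures), 11 had 1 mouse far from the other 8, measured as the gap to the nearest mouse over the range of the group. Chance gives about 1 in 20 groups, or 9.25. In log2 intensity, Tff3 was high in Veh 8 (7.41, nearest 4.54) and Cyp4a10 in Con 9 (7.11, nearest 4.39), and Etfbkmt was high in Con 3 (8.24). Low values were those of Tdo2 in Veh 2 (11.34), Mbl2 in Dex 5 (7.84), Rarres2 in Dex 2 (9.82), Psmb8 in Con 3 (6.77), Dnajb13 in Veh 6 (2.72), Hsd3b6 in Con 9 (5.28), Glud1 in Con 9 (8.40) and Abcc2 in Dex 5 (4.24). Con 9 appears 3 times, Con 3 and Dex 5 appear 2 times each, and none of the array measures had such a mouse.

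Other groupings of the same mice were drawn to see how often as many probes pass. For Dex vs Veh 2 of 100 groupings, the actual groups included, gave at least 18 probes, and the highest other gave 20. For Veh vs Con 1 of 100, the actual groups, reached 262, and the highest other gave 1. For Dex vs Con 1 of 100 reached 1115, and the highest other gave 3. The share of groupings lay under the 0.05 level for the 3 counts, without adjustment over the comparisons. This argues against chance for Veh vs Con and Dex vs Con, where no other grouping came near the actual count. For Dex vs Veh another grouping passed more probes than the actual groups, so chance is not excluded there.

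Against Con, more probes fell than rose, with 30.9% of the changed probes higher in Veh and 19.8% in Dex. With quantile normalization the share was 52.9% for Veh (46.0% to 67.4% over the sets that leave out 1 array), but this method evens out the arrays whatever made them differ, so it cannot tell scaling from a real fall, and scaling stays open for Veh. In Dex it was 29.3% (27.1% to 32.3%), which argues against scaling as the whole cause there. With the Gapdh 3' to 5' ratio in the fit the share was 46.7% for Veh, but only 75 probes passed, so RNA quality stays open for Veh. For Dex the share was 19.8%. The Gapdh ratio did not pass the test between Dex and Con (exact permutation adjusted p = 0.223), so adding it could hardly move this share. The fit therefore cannot decide on RNA quality for Dex. A real fall of many transcripts under both treatments stays open as an untested biological explanation.

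PPARA targets were higher in Veh than in Con. Array scaling is argued against by an adjusted p of 3.93e-05 with quantile normalization, and a few high arrays by the 7 of 9 Veh mice whose list score lay above the highest Con mouse. Probes that bind several Cyp4a transcripts are argued against as the whole cause, since without the Cyp4a members the list kept a camera p of 1.19e-07 (at most 9.43e-07 with any 1 array left out), with 16 of 18 members higher and a median of 0.35. A response of the liver to the Veh treatment is a hypothesis found and tested on the same data, and with an estimated correlation between genes the adjusted p of the list was 0.0621.

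Interferon-stimulated genes were lower in Dex than in Veh (adjusted p = 0.331 with an estimated correlation), and 2 Veh mice had high list scores (Veh 7 at 2.40 and Veh 2 at 1.56). High Veh mice are argued against as the whole cause, since the score in Dex also lay below that in Con (difference -0.81). The exact permutation p was 2.47e-04, and at most 5.35e-04 with 1 array left out. Relative to the median gene of each array the difference was -0.56 (exact p at most 4.52e-04 with 1 array left out). The camera test of the list in Dex vs Con, however, had an adjusted p of 0.0648 (0.652 with an estimated correlation). With the beta-actin ratio in the fit the list kept a camera adjusted p of 1.10e-05 in Dex vs Veh. This argues against a linear effect of that ratio as the whole cause. The ratio comes from 1 control transcript and itself differed between Dex and Veh, so RNA quality stays open. Fewer macrophages cannot be told apart from a lower interferon response. The interferon score fell further than the macrophage score (difference -0.66, exact p = 0.0297), which met the bound written beforehand, but the exact p ranged from 0.00761 to 0.0585 with 1 array left out and missed the threshold in 6 of those sets, with the highest value without Veh 7, a spread that was examined after the 0.0297 was seen. The Dex treatment itself stays open as an untested biological explanation.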

How the results depend on the processing

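The beta-actin ratio and the array median as covariates, the set without the least correlated arrays (Con 9, Veh 7 and Dex 2), leaving out each array for the lists, and the number of lists past the test were chosen after the data were seen, and the other alternatives were planned. The lists followed through each alternative are those that passed, the growth hormone list and the interferon list in Dex vs Con, a choice also made after the results were seen. For changes below without a stated reason, the cause was not tested. The floor at percentile 1 or 20 kept each count within 1.5 times and each followed list on its side of the threshold. Robust moderation, run for probes and named genes only, kept each count within 1.5 times, and the mean of a gene's probes, run for lists only, kept each followed list on its side. Over named genes and alternatives, 3725 of 4207 values kept direction and side of the threshold, 407 lost the call, 46 gained it and 29 turned, all of the latter in genes not called. Of the called named genes, 0 of 12 in Dex vs Veh, 3 of 21 in Veh vs Con and 12 of 24 in Dex vs Con passed under each alternative other than leaving out single arrays, and none turned. Of the list values 827 of 945 kept side and direction. Low signal limits what is seen: 5.18% to 15.1% of the probes of an array were at or under the floor.

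Quantile normalization gave 85 probes in Veh vs Con and 658 in Dex vs Con. It turned Tat in Veh vs Con (-0.18) and Actb in Dex vs Con (-0.15). The adjusted p was 0.141 for acute phase and 0.00866, downwards, for growth hormone in Veh vs Con, and in Dex vs Con 0.546 for gluconeogenesis, 0.562 for PPARA, 0.249 for lipogenesis and 0.0362 for interferon. No filter, with more probes to adjust over, gave 7 probes in Dex vs Veh and 116 in Veh vs Con, 9 lists in Dex vs Veh, and in Dex vs Con 0.104 for gluconeogenesis and 0.158 for PPARA. The stricter filter, with fewer probes and list members, gave 55 probes in Dex vs Veh. It ended PPARA (0.0667), complement (0.0667) and macrophage (0.0621) in Dex vs Veh, interferon in Veh vs Con (0.0892), and gluconeogenesis (0.0959), PPARA (0.0864) and lipogenesis (0.0512) in Dex vs Con, and left 3 lists in Dex vs Veh and 4 in Dex vs Con.

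With only the 2 groups compared in the fit, and so fewer arrays, 1 probe passed in Dex vs Veh and 656 in Veh vs Con, with 0.0584 for complement in Dex vs Veh and 0.00502 for interferon in Dex vs Con. Array weights gave 4 probes in Dex vs Veh and 1158 in Veh vs Con, with Actb at -0.034 in Dex vs Con. The camera adjusted p was then 0.0538 for interferon and 0.110 for MHC class II in Veh vs Con. In Dex vs Con it was 0.0508 for PPARA and 0.0409 for interferon. No mean trend gave 5 probes and 0.0658 for complement in Dex vs Veh, and turned growth hormone in Dex vs Con (0.978). The Gapdh ratio gave 75 probes in Veh vs Con, Tat at -0.13 in Veh vs Con, Actb at -0.082 in Dex vs Con, 0.149 for complement and 9 lists in Dex vs Veh, and turned growth hormone in Dex vs Con (0.943). An adjusted p under 0.01 left 1, 41 and 324 probes in Dex vs Veh, Veh vs Con and Dex vs Con, and a 2-fold minimum left 9, 77 and 305.

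An estimated correlation left 0 lists in each comparison. The adjusted p was 0.331 for glucocorticoid, PPARA, complement and interferon and 0.396 for macrophage in Dex vs Veh. In Veh vs Con it was 0.137 for PXR and CAR, 0.0621 for PPARA, 0.474 for lipogenesis, 0.574 for acute phase and interferon and 0.544 for MHC class II. In Dex vs Con it was 0.4931 for glucocorticoid, gluconeogenesis and acute phase, 0.0582 for PXR and CAR, and 0.592 for PPARA, lipogenesis and cholesterol. With fry 2, 1 and 1 lists passed in the 3 comparisons. Its adjusted p was 0.130 for glucocorticoid and macrophage and 0.0645 for PPARA in Dex vs Veh. In Veh vs Con it was 0.140 for PXR and CAR, 0.178 for lipogenesis, 0.451 for acute phase and interferon and 0.377 for MHC class II. In Dex vs Con it was 0.252 for glucocorticoid, 0.284 for gluconeogenesis, 0.633 for PPARA, 0.474 for lipogenesis, 0.463 for cholesterol and 0.192 for acute phase.

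The beta-actin ratio gave 1 probe in Dex vs Veh and 33 in Veh vs Con, 0.154 for complement in Dex vs Veh, 0.0869 for interferon and 0.0566 for MHC class II in Veh vs Con, and turned growth hormone in Dex vs Con (0.965). The array median gave 109, 21 and 468 probes in the 3 comparisons, Tat at -0.046 in Veh vs Con, Actb at -0.51 in Dex vs Con, 0.124 for complement in Dex vs Veh, 0.248 for acute phase in Veh vs Con, and in Dex vs Con 0.0524 for gluconeogenesis, 0.148 for PPARA, 0.0504 for lipogenesis and 0.0475 for interferon. Without the least correlated arrays 3 probes passed in Dex vs Veh and 126 in Veh vs Con, Igfbp1 was -0.044 in Dex vs Veh, Mt1 0.12 in Veh vs Con, and the adjusted p was 0.0686 for macrophage in Dex vs Veh, 0.129 for interferon and MHC class II in Veh vs Con, and 0.0587 for gluconeogenesis, 0.0532 for PPARA and 0.0133 for interferon in Dex vs Con. The exact test on ranks gave an adjusted p of 0.0710 for the trimmed mean in Dex vs Con.

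With 1 array left out, 4 (without Dex 5) to 124 (without Dex 6) probes passed in Dex vs Veh, 85 (without Veh 5) to 586 (without Veh 9) in Veh vs Con and 785 (without Dex 1) to 1488 (without Dex 8) in Dex vs Con, with 4 to 8 lists in Dex vs Veh. The adjusted p of lists that changed ran from 0.00366 to 0.133 for complement in Dex vs Veh, 0.00721 to 0.111 for MHC class II and 1.90e-04 to 0.0827 for interferon in Veh vs Con. In Dex vs Con it ran from 0.0110 to 0.170 for PPARA, 1.84e-04 to 0.0757 for lipogenesis, 0.00456 to 0.0501 for gluconeogenesis, 0.0146 to 0.118 for interferon and 0.725 to 0.999 for growth hormone, which turned in 8 sets. Actb in Dex vs Con ran from -0.20 to 0.27, Igfbp1 in Dex vs Veh from -0.079 to 0.96, Mt1 in Veh vs Con from -0.77 to 0.34 and Tat in Veh vs Con from -0.038 to 0.16. The call held in each of the 27 sets for 3 of 12 named genes in Dex vs Veh, 13 of 21 in Veh vs Con and 18 of 24 in Dex vs Con. In Dex vs Veh it held in 24 for Sult1d1 (lost without Dex 2, 0.0531, Dex 3, 0.0564, or Dex 5, 0.0654), 22 for Psme1 (lost without Veh 2, 0.0594, Veh 5, 0.0644, Dex 2, 0.0532, Dex 3, 0.0655, or Dex 5, 0.0654) and 15 for Tff3 (highest adjusted p 0.0807, without Veh 2). It held in 10 for Psmb8 (0.0807, without Veh 2), 8 for Gatm (0.0808, without Veh 8) and Cd1d1 (0.0807, without Veh 2), 6 for Igtp (0.0972, without Veh 2) and Rarres2 (0.0898, without Veh 5) and 5 for Arpc2 (0.0826, without Veh 3). In Veh vs Con it held in 26 for Apbb1 (lost without Con 3, 0.0502), 25 for Hnrnpl (without Veh 5, 0.0603, or Con 3, 0.0507), 22 for Eci1 (without Con 1, 0.0515, Con 6, 0.0517, Con 7, 0.0552, Veh 2, 0.0609, or Veh 5, 0.0627) and 22 for Nxf1 (without Con 1, 0.0543, Con 3, 0.0507, Con 7, 0.0519, Veh 2, 0.0521, or Veh 5, 0.0627). It held in 17 for Crip1 (highest 0.0658, without Veh 4) and Hsd3b6 (0.0817, without Veh 2), 16 for Tmsb10 (0.0798, without Veh 2) and 15 for Mgst3 (0.0957, without Veh 5). In Dex vs Con it held in 19 for Elovl6 (highest 0.0654, without Dex 1) and Tdo2 (0.0885, without Dex 2), 12 for Igfbp1 (0.109, without Dex 1), 26 for Dio1 (lost without Dex 4, 0.0525) and 25 for Sc5d (without Dex 1, 0.0550, or Dex 2, 0.0502) and Hsd3b5 (without Dex 1, 0.0766, or Dex 2, 0.0738).

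Of the lists that did not pass, some did under an alternative other than leaving out single arrays. In Dex vs Veh these were acute phase (Gapdh ratio, 8.22e-05; beta-actin ratio, 4.20e-05; array median, 0.0116; stricter filter, 0.0204), PXR and CAR (beta-actin ratio, 0.0480; array median, 0.0349), MHC class II (no filter, 0.0390; Gapdh ratio, 0.0256), B cell and skeletal muscle markers (no filter, 0.0408), and with the Gapdh ratio gluconeogenesis (0.0256), NF-kB (0.0453) and immediate early genes (0.0164). In Veh vs Con they were growth hormone, downwards (quantile, 0.00866), cholesterol (2 groups, 0.0465; array weights, 0.0429; Gapdh ratio, 0.00758; beta-actin ratio, 0.00998), NF-kB (no filter, 0.0413), complement (array weights, 0.0429) and macrophage (Gapdh ratio, 0.0413). In Dex vs Con they were complement, downwards (quantile, 9.94e-04), interferon, downwards (quantile, 0.0362; 2 groups, 0.00502; array weights, 0.0409; array median, 0.0475; without the least correlated arrays, 0.0133), and with the Gapdh ratio immediate early genes and macrophage, downwards (0.0482 each). Without passing, lists turned 22, 36 and 62 times in the 3 comparisons.

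With the replicate number as a block, 3 probes passed in Dex vs Veh, 311 in Veh vs Con and 1120 in Dex vs Con, with 0.0536 for complement in Dex vs Veh and 0.0622 for PPARA in Dex vs Con. The labels do not tie same-numbered mice together, and the cause was not tested.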

Other observations

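The mice and genes here were picked after the data were seen, and are given as values without a test.

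Single mice stood far from their groups for some named genes, and mice were not regrouped by them. The glucocorticoid receptor target Fkbp5 was at 11.53, 11.11 and 10.90 (log2 intensity) in Dex 1, Dex 2 and Dex 3, against a Dex mean of 8.26 ± 2.23 (SD, n = 9), and Tat was at 13.94, 13.90 and 13.50 in the same mice, against 12.57 ± 0.95. Interferon-inducible Igtp was at 11.65 in Veh 7 and 9.56 in Veh 2, against a Veh mean of 7.68 ± 1.80 (SD, n = 9).

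The male-biased steroid dehydrogenase Hsd3b5 split the Veh mice. It lay at 2.38, 2.63, 3.12 and 6.12 in Veh 7, Veh 2, Veh 4 and Veh 5 and between 9.27 and 9.94 in the other 5. Cyp7b1 was lowest and Cyp2b9 highest in the same 4 mice. In Con it lay between 10.07 and 10.83, and in Dex between 1.38 and 9.40.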
